A study of Mus musculus with 59 samples.

How the data were processed

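CTCF ChIP-seq was deposited for mouse cells in 15 groups and SMARCA5 ChIP-seq for 1 group. The CTCF groups were day 10 reprogramming cells with OSKM, with OSKM and Ctcf, and with OSKM, Ctcf and an shRNA against Smarca5. Further groups were wild-type and Smarca5 knockout ESCs of the E14 line, and day 0, Thy1+, SSEA1- Thy1-, SSEA1+ and day 12 Oct4-GFP+ cells with an shRNA against luciferase or Ctcf. Thy1+ samples were taken on days 3 and 9, and the SSEA1- Thy1- and SSEA1+ samples on days 6 and 9. SMARCA5 was mapped through an overexpressed tagged protein in ESCs. The 28 input samples had no lists and were not used here.

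Per the submitters' processing notes, the tools were FastQC, Trim Galore, Bowtie2, SAMtools, Picard, bedtools, MACS2, HOMER and deepTools, and the genome build was mm10 (GRCm38). Versions, roles, thresholds and the way samples were pooled are not given in the sources used here. Each deposited file is a list of intervals of 400 bp, and the score that the authors' files give for each peak is 0 in every line. Peaks could therefore not be ranked or filtered by strength. Within the day 10 lists, within the 8 lists of the sorted cells and within the 3 ESC lists, peaks have common start positions, while the 2 day 0 lists have their own. The lists thus fall into 4 coordinate sets, and how positions were harmonised is not stated. Sharing of positions within a set can raise overlaps there, and 400 bp intervals with no signal hide partial loss of binding.

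Samples were grouped by title. For the day 3 Thy1+ samples, the description and source name contradict the title on which received Ctcf shRNA, and the lists were used under the titles' grouping. A first-list peak counted as kept when it overlapped a peak of the second list by at least 1 bp. An alternative required a reciprocal overlap of 50%, which for these widths means starts at most 200 bp apart. Shares have Wilson 95% intervals. Differences between classes of peaks within a list have 95% intervals from 1000 resamples of 21 chromosomes. These intervals describe the lists and not the spread between cultures. The 5 knockdown pairs were tested with an exact two-sided sign-flip test, whose smallest p is 0.063. Background overlap of SMARCA5 and CTCF was taken from SMARCA5 peaks shifted by 4 distances between 5 and 100 kb.

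The recurrence of a site is the number of control lists of other coordinate sets that hold it (0 to 3), taking the day 0 control, day 10 OSKM, SSEA1- Thy1- control and wild-type ESC lists as representatives. Somatic-type sites were in the day 0 and Thy1+ control lists and in neither the day 12 control nor the wild-type ESC list, and pluripotent-type sites the reverse. Classes with fewer than 20 sites were given no value.

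Genes came from a RefSeq table of GRCm38.p6, the same build as the files. It has gene spans without strand, so peaks within 10 kb of a gene span, or inside it, were assigned to the gene in place of the transcription start sites planned before the data were examined. Exons and introns were not used here. The 10 gene lists were fixed before the data were examined: pluripotency network (30 genes), fibroblast and mesenchymal (30), epithelial (20), trophoblast and primitive endoderm (16), neural (16), haematopoietic (16), Hox (39), imprinted (24), clustered protocadherins (58), and CTCF, cohesin and ISWI remodeller genes (20). Every listed gene was matched to the table, with Nespas found as Gnasas1. The kept share of a list's peaks was set against 10000 random lists of protein-coding genes matched on the number of first-list peaks, drawn from 21631 genes. A percentile describes these lists of peaks and is not a p-value. A peak near several members counts for each.

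Genes to be named were chosen by a rule fixed before the data were examined. For each comparison it takes the 10 highest-scoring peaks found only in either list and having a gene within 10 kb, and in each gene list up to 4 members, in list order, that kept no peak or had a peak only in the second list. Since all scores and widths are equal, the first part falls to the first such peaks along chromosome 1. Any other named gene is stated as chosen after its values were seen. The share of peaks with a CTCF motif was not computed because no genome sequence was used here.

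On simulated lists built from the wild-type ESC peaks (83173), a true kept share of 73.7% was recovered as 73.8%, and a true difference of -20 points as -19.9. Of 20 gene lists with planted losses, 20 lay below percentile 2.5, and of 20 without, 0 did, where 0.5 are expected. For these lists kept counts were drawn separately for each of a set of scattered genes. Neighbouring genes thus shared no kept peak and recurrence played no part, so clustered lists were not tested. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.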

Results

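CTCF binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse fibroblasts on their way to pluripotency and in embryonic stem cells (ESCs). CTCF is a zinc-finger protein that anchors chromatin loops and blocks contacts between enhancers and promoters. Reprogramming was driven by OSKM, the transcription factors Oct4, Sox2, Klf4 and c-Myc. The series held 59 samples, of which 31 were ChIP samples and 28 were input DNA. The ChIP samples had 16 deposited peak lists, 15 for CTCF and 1 for SMARCA5, the ISWI-family ATPase that slides nucleosomes. Each group had 1 list, whatever its number of samples (1 to 3), so no difference between lists has a replicate check and shares carry Wilson 95% intervals that cover counting error only. Depth per library was not given in the sources used here. Peak lists do not measure mRNA, so the level of the targeted gene, Ctcf or Smarca5, could not be checked in any sample.

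The control lists followed reprogramming from day 0 cells through Thy1+, SSEA1- Thy1- and SSEA1+ sorted cells to day 12 Oct4-GFP+ cells, which have switched on a reporter of pluripotency. Thy1 is a fibroblast surface protein, and SSEA1 marks cells moving towards pluripotency. The day 0 control list held 28838 peaks, the sorted control lists between 50890 and 53043, the day 10 OSKM list 43356 and the wild-type ESC list 83173. Between 51.3% and 59.9% of the peaks of each list lay inside the span of a protein-coding gene. Sites found in the day 12 and ESC control lists and in neither the day 0 nor the Thy1+ control list are called pluripotent-type here, and they numbered 9149, which was 17.2% of the day 12 control list. The reverse, somatic-type sites, numbered 230 in the Thy1+ control list (0.436%).

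Pluripotent-type sites were dense at genes of the pluripotency network. They made up 32 of 88 peaks near these genes (36.4%), above each of 10000 random lists of genes matched on peak number (median 15.9%), and 19 of the 30 genes had at least 1. Examples are Esrrb with 3 and Nanog with 2, both transcription factors of the ESC network, and Dnmt3b, a DNA methyltransferase, with 3, genes chosen after their values were seen. Genes of the epithelial list, which covers the mesenchymal-to-epithelial transition, also had many (17 of 56 peaks, 30.4%, percentile 99.7). Genes of the fibroblast and mesenchymal list had 3 of 52 (5.77%, percentile 3.6), and the Hox genes, the clustered regulators of body patterning, had 0 of 71. A Hox gene or a clustered protocadherin shares peaks with its neighbours, and here and below such a peak is counted once per gene. Random lists of scattered genes therefore vary less than these clusters would. The shorter day 0 list can by itself place weaker sites among the pluripotent-type ones.

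**Figure D1:**
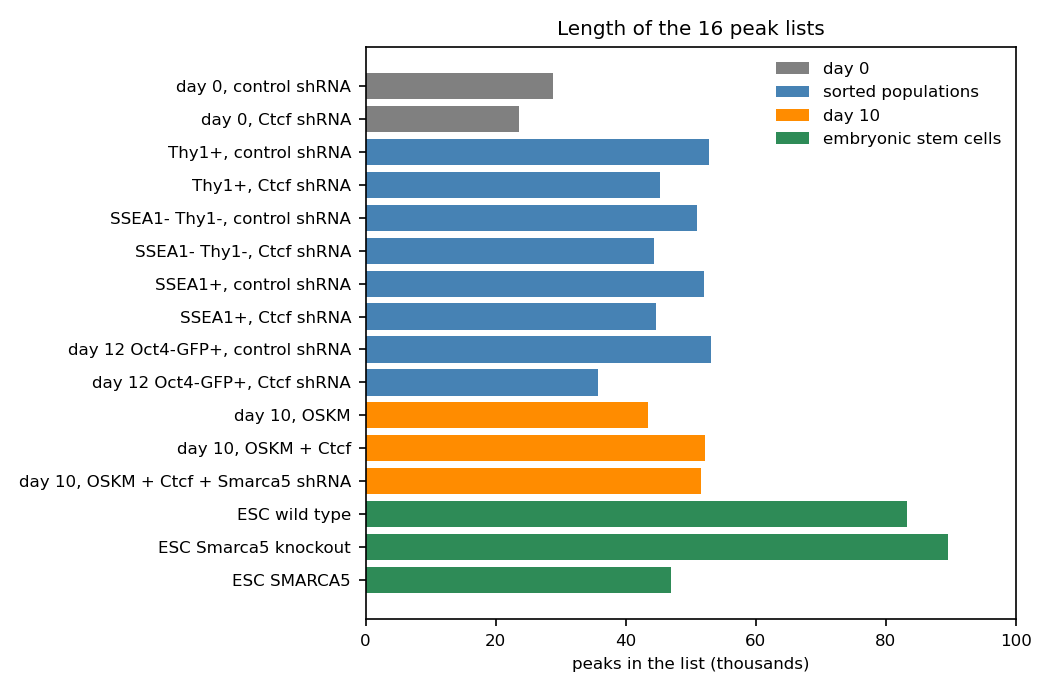
Number of peaks (x axis) in each of the 16 lists, 1 bar per list, coloured by the set of lists that share peak coordinates. The Ctcf shRNA bar is shorter than its control bar in each of the 5 populations, and the Smarca5 knockout ESC bar, at 89567 peaks, is the longest.

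The first comparison asked which sites are added to the CTCF list when Ctcf is overexpressed during reprogramming. On day 10, the list of cells with OSKM and Ctcf held 52252 peaks, 20.5% more than with OSKM alone. Of the 43356 peaks with OSKM alone, 99.7% (99.6 to 99.7) were also found with added Ctcf, 143 were not, and 9039 peaks appeared only with added Ctcf. Within the 10 gene lists, the genes that had a CTCF peak only with added Ctcf were Nr0b1, a nuclear receptor of the pluripotency network, Thy1, the tight-junction gene Cldn6, Hoxc13, and the cohesin genes Smc1a and Wapl, each with 1 peak. Of the peaks near the pluripotency network, 12 of 66 were present only with added Ctcf (18.2%, percentile 47.8, at the random median), while the shares were low near imprinted genes (7.55%, percentile 1.61), trophoblast and primitive endoderm genes (6.98%, percentile 2.35) and clustered protocadherins (11.4%, percentile 0.09). In the 10 gene lists, no gene with a peak under OSKM alone was without one under added Ctcf.

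Peaks that appeared only with added Ctcf were rarely day 0 sites, and they were ESC sites less often than the peaks shared by both day 10 lists. Of these 9039 peaks, 75.6% overlapped a wild-type ESC peak and 7.43% a day 0 control peak, a difference of 68.2 percentage points (66.9 to 69.5, resampling chromosomes). Among the 43213 peaks shared by both day 10 lists, 95.7% were ESC peaks and 61.3% were day 0 peaks, a difference of 34.5 points (33.9 to 34.9). Along chromosome 1 (mm10), the first peaks present only with added Ctcf lay in Xkr4 at 3671348 to 3671747, in Rp1 at 4382775 to 4383174 and in Rgs20 at 5019517 to 5019916. The ESC list is the longer of the 2 references, so the difference within a class cannot be read by itself. Peaks missing from the OSKM list may be weaker sites, and the shorter day 0 list can miss weaker sites more often. The contrast between peak classes can follow from this alone, and the lists hold no peak strength.

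The second comparison asked whether these sites need Smarca5, by adding an shRNA against Smarca5 to OSKM and Ctcf. The list with Smarca5 shRNA held 51635 peaks, a change of -1.18%. It kept 98.3% (98.2 to 98.4) of the 52252 peaks, leaving 897 out and adding 280. Sites that had appeared only with added Ctcf were kept in 93.6% of cases (93.0 to 94.0) and sites shared with OSKM alone in 99.3% (99.2 to 99.3). None of the 10 gene lists had a member that went from 1 or more peaks to 0 or from 0 to 1 or more. Pluripotency network genes kept 66 of 66 peaks, fibroblast genes 72 of 72, Hox genes 91 of 91 and imprinted genes 51 of 53. Clustered protocadherins kept 420 of 420 (above each random list, or percentile 98.2 with recurrence accounted for). New peaks near the pluripotency network were 2 of 68 (percentile 98.0). Peaks absent with Smarca5 shRNA included those in Slco5a1 (chromosome 1, 12992558 to 12992957) and Paqr8 (20925343 to 20925742).

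Day 10 sites at which ESCs hold SMARCA5 were kept in 98.9% of cases and the others in 97.5%, a difference of 1.44 points (1.16 to 1.74), with the same sign on 20 of 20 chromosomes. That difference disappeared when sites were compared within classes of equal recurrence, that is, found in the same number of control lists from other coordinate sets (-0.0491 points, -0.280 to 0.179), an alternative chosen after the data were seen. The wild-type ESC list is among those control lists, and 86.1% of SMARCA5 peaks hold one of its CTCF peaks. Recurrence and SMARCA5 are thus partly the same trait, and this comparison cannot tell which of them goes with the 1.44 points. The Smarca5 shRNA group had 1 ChIP sample.

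The third comparison asked what CTCF binding looks like in ESCs that lack Smarca5. The knockout list was longer than the wild-type list, with 89567 against 83173 peaks, an increase of 7.69%. Of the wild-type peaks, 97.1% (97.0 to 97.2) were kept, 2397 were absent from the knockout list and 8791 peaks appeared only there. The neural list kept 39 of 40 peaks (percentile 56.2), and 8 of its 47 knockout peaks were absent from wild type (17.0%, percentile 97.0), both inside the central 95% of random lists. Within it Neurod1, a proneural transcription factor, had 1 peak in wild type and 0 in the knockout, while Otx2, a homeobox factor of the anterior nervous system, went from 0 to 2. Itgam, a myeloid integrin, went from 0 to 1. Pluripotency network genes kept 149 of 152 peaks (98.0%, percentile 87.0), and fibroblast genes kept 100 of 100 (percentile 98.4, or 95.8 with spans widened by 2.5 kb). Clustered protocadherins kept 543 of 544 (above each random list, or percentile 99.8 with recurrence accounted for). Of their 555 knockout peaks, 12 were absent from wild type (2.16%, below each random list). Near the pluripotency genes, 13 of the 162 knockout peaks were absent from wild type (8.02%, percentile 18.4), among them a peak inside Tfcp2l1 (chromosome 1, 118658540 to 118658939), a gene chosen after its values were seen. Both lists come from 1 ChIP sample each.

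SMARCA5 itself was mapped in ESCs with a tagged, overexpressed protein, and its 46965 peaks lay mostly on CTCF sites. A wild-type CTCF peak was present at 86.1% of SMARCA5 peaks (85.7 to 86.4), against 4.62% to 5.59% when the SMARCA5 peaks were shifted by 5 to 100 kb. Conversely, 48.6% of wild-type CTCF peaks (48.3 to 48.9) held a SMARCA5 peak, against 2.63% to 3.09% after shifting. Of the 6547 SMARCA5 peaks without CTCF in wild type, 47.5% (46.2 to 48.7) held a CTCF peak in the Smarca5 knockout list. At the imprinting control region upstream of H19 on chromosome 7, SMARCA5 had both of the peaks that CTCF had in wild-type ESCs, at 142580539 to 142580938 and 142581767 to 142582166. The overlapping SMARCA5 and CTCF peaks have identical coordinates, so the lists were harmonised before deposit in a way the sources used here do not state, and this can raise the overlap.

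CTCF sites with SMARCA5 were kept slightly more often in the Smarca5 knockout than sites without it. The shares were 98.0% of 40418 and 96.3% of 42755, a difference of 1.78 points (1.48 to 2.10), with the same sign on 20 of 20 chromosomes. Peaks that appeared only in the knockout list held SMARCA5 in 35.3% of cases (34.4 to 36.3), peaks found only in wild type in 33.1% (31.3 to 35.0), and peaks in both lists in 49.1% (48.7 to 49.4). Within classes of equal recurrence, the difference in kept share shrank to 0.676 points (0.359 to 0.995).

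The remaining comparisons asked how CTCF occupancy responds to an shRNA against Ctcf at each stage, with an shRNA against luciferase as control. In all 5 populations the Ctcf shRNA list was shorter, with changes in length of -18.2% in day 0 cells, -14.2% in Thy1+ cells, -13.0% in SSEA1- Thy1- cells, -14.2% in SSEA1+ cells and -32.5% in day 12 Oct4-GFP+ cells. Over the 5 pairs the geometric mean ratio of list lengths was 0.812, with an exact two-sided sign-flip permutation test p = 0.063, the smallest p that 5 pairs allow. The planned difference between the share of control peaks kept and the share of Ctcf shRNA peaks found in the control list (-28.1 to -12.2 points, mean -16.7) restates the list lengths, since both shares have nearly the same numerator, and is no separate test. This design cannot reach 0.05.

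Sites that cells of all stages share were kept best. Sites found in all 3 control lists of other coordinate sets were kept in 98.6% of cases in Thy1+ cells, 97.8% in SSEA1- Thy1- cells, 97.8% in SSEA1+ cells, and 79.0% (78.4 to 79.4) in day 12 cells. Sites found in none of them were kept in 50.1%, 49.4%, 45.0% and 36.6% of cases. In day 0 cells the corresponding shares were 78.9% and 8.27%. Among sites that the 4 sorted control lists have in common, 38044 in number, 65.1% were kept in all 4 Ctcf shRNA lists and 306 (0.804%) were absent from all 4.

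**Figure D2:**
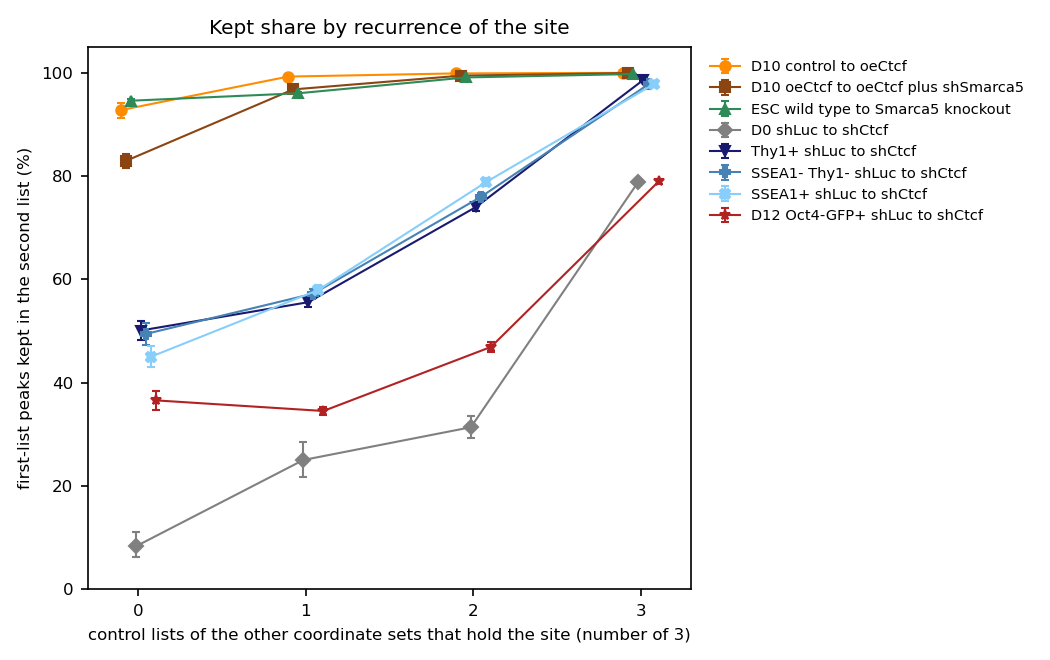
Share of first-list peaks kept in the second list (%, y axis) against the number of control lists of the other coordinate sets that hold the site (x axis), 1 line per comparison, with Wilson 95% intervals. The day 12 line ends at 79.0% for sites held in all 3 and lies at 36.6% for sites held in none, and the ESC line runs between 94.6% and 99.8%.

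In day 0 cells, 73.3% of 28838 control peaks (72.8 to 73.8) were kept with Ctcf shRNA, 7695 were absent and 2457 were added. Pluripotency network genes kept 25 of 32 peaks and fibroblast genes 27 of 35, both inside the range of random lists (percentiles 63.9 and 58.9). Vim, an intermediate filament gene of mesenchymal cells, Twist1, Fbn1 and S100a4 kept none of their peaks, nor did Lin28a, Dppa2, Dppa3 and Nr5a2 of the pluripotency network, and neither did H19 with its 1 peak at the imprinting control region. Fbn1, S100a4 and Dppa2 each had 1 peak elsewhere with Ctcf shRNA. Hox genes kept 47 of 51 peaks (92.2%, percentile 99.9). Clustered protocadherins, the neuronal adhesion genes whose promoter choice depends on CTCF, kept 117 of 175 (66.9%, percentile 2.98, or 11.8 with recurrence accounted for), inside the central 95%. New peaks were frequent at protocadherins, 28 of 145 (19.3%, percentile 99.995), and at fibroblast genes, 8 of 35 (22.9%, percentile 99.3). The gene Smarca5 had a peak only with Ctcf shRNA. These 2 lists do not share coordinates with each other, unlike the lists of the sorted cells, so their kept share is not on the same footing.

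In Thy1+ cells, 81.1% of 52800 control peaks (80.7 to 81.4) were kept, 9997 were absent and 2490 were added. The gene Thy1, which codes for the protein used to sort these cells, kept 0 of 2 peaks and had 1 elsewhere. Klf5 and Tfcp2l1, transcription factors of the pluripotency network, each had 1 peak with control shRNA and 0 with Ctcf shRNA, as did Cldn6, Krt8, Sox17 and Sox7. Network genes together kept 47 of 63 peaks (74.6%, percentile 13.1). Hox genes kept 73 of 76 (96.1%) and clustered protocadherins 425 of 448 (94.9%), both above each of the random lists, with shared peaks counted once per gene. With recurrence accounted for, the Hox genes lay at percentile 97.3, inside the central 95%, and the protocadherins stayed above each list. The labels of the day 3 samples of this population conflict on which is control and which is Ctcf shRNA, so a crossed library in each Thy1+ list cannot be excluded.

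In SSEA1- Thy1- cells, 82.0% of 50890 control peaks (81.7 to 82.4) were kept, 9139 were absent and 2536 were added. Klf5, Tfcp2l1 and Nr0b1 kept none of their peaks, with 1 each in the control list, while Klf2, another factor of the network, had its 1 peak only with Ctcf shRNA. Network genes as a group kept 48 of 59 (81.4%, percentile 39.1). Clustered protocadherins kept 371 of 445 (83.4%, percentile 83.8) and Hox genes 68 of 74 (91.9%, percentile 98.9). With recurrence accounted for, the percentiles were 97.75, in the upper tail, and 71.1. The genes for CTCF, cohesin and ISWI remodellers kept 53 of 75 (70.7%, percentile 1.08), and Smc1a, a core cohesin subunit, kept 0 of 2. With gene spans widened by 2.5 or 50 kb their percentile was 4.76 or 2.55. Igf2r, an imprinted receptor gene, and Krt7 and Sox17 from the extraembryonic list kept none.

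In SSEA1+ cells, 82.0% of 51978 control peaks (81.7 to 82.3) were kept, 9359 were absent and 2011 were added. The pluripotency network kept 50 of 71 peaks (70.4%), at percentile 0.49 of the random lists, whose median was 83.1%. Tfcp2l1 kept 0 of 2 peaks, Nr0b1 0 of 1 and Dppa4, a chromatin-associated factor of early embryos, 0 of 1. Fibroblast genes kept 43 of 54 (79.6%, percentile 28.6), although Thy1 kept 0 of 1. Clustered protocadherins kept 392 of 428 (91.6%, above each random list), and Hox genes 67 of 79 (84.8%, percentile 71.1), with shared peaks counted once per gene. With gene spans widened by 50 kb the network's percentile was 3.64. It was 4.63 with every gene given the same weight, 5.75 without the 3 members with the most peaks (Jarid2, Tet1 and Dnmt3b), 21.6 without the 5 with the most, and 17.3 without the 3 whose removal raises the share most (Tfcp2l1, Dnmt3l and Jarid2). Apart from the 50 kb span, these settings and genes were chosen after the values were seen. With any single member left out the percentile was at most 2.095. With recurrence accounted for, also chosen after the data were seen, it was 2.34. The low share in SSEA1+ cells thus rests on few genes, though not on a single one.

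In day 12 Oct4-GFP+ cells, 58.6% of 53043 control peaks (58.1 to 59.0) were kept, 21981 were absent and 4781 were added. The difference from the mean of the other sorted populations, 81.7%, was -23.1 points (-23.9 to -22.6, resampling chromosomes). The pluripotency network kept 37 of 88 peaks (42.0%), at percentile 0.08 of the random lists, whose median was 58.0%. With the recurrence of each site accounted for, a comparison chosen after the data were seen, the percentile was 2.82, inside the central 95%. Of its 29 genes with a control peak, 10 kept none, among them Klf2, Klf5, Tfcp2l1 and Zfp42, a zinc-finger marker of naive pluripotency, and 5 kept each of theirs. Dppa2 kept 0 of 4 peaks and Tdgf1 0 of 3, genes chosen after their values were seen. The reprogramming factor genes, also chosen after the values were seen, kept 2 of 3 at Pou5f1, 2 of 2 at Sox2 and 1 of 1 at Klf4, and Nanog kept 2 of 4.

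The other gene lists of day 12 cells lay inside the range of random lists, except the clustered protocadherins. These kept 341 of 484 peaks (70.5%, above each random list), with peaks shared by neighbouring genes counted once per gene. Fibroblast genes kept 29 of 52 (55.8%, percentile 33.1), epithelial genes 28 of 56 (50.0%, percentile 9.32) and Hox genes 43 of 71 (60.6%, percentile 63.6). Trophoblast and primitive endoderm genes kept 65.0%, neural genes 58.1%, haematopoietic genes 63.0%, imprinted genes 52.2% and CTCF, cohesin and ISWI genes 52.5%. Epcam, an epithelial adhesion gene, kept none, and neither did Gata6, Pax6, Sox1 and Hoxb4. In the CTCF, cohesin and ISWI list, whose share lay at percentile 14.15, 7 of 20 genes kept none, including Ctcf itself, Rad21, Smc1a and Mau2. Ctcf and Smc1a each had 1 peak elsewhere with Ctcf shRNA. Both peaks at the H19 imprinting control region were absent, as were the peaks of Peg10, Sgce and Gnasas1.

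**Figure D3:**
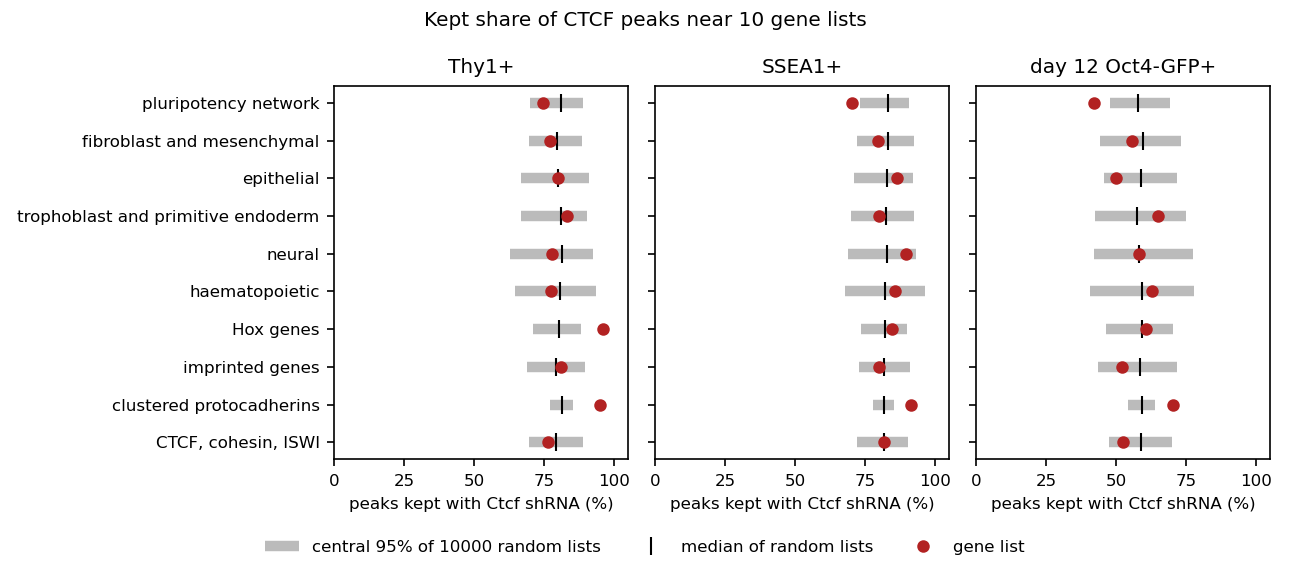
Share of control peaks kept with Ctcf shRNA (%, x axis) near each of the 10 gene lists in Thy1+, SSEA1+ and day 12 Oct4-GFP+ cells, with the median and central 95% of 10000 random gene lists. The pluripotency network lies at 74.6%, 70.4% and 42.0%, below the random range in SSEA1+ and day 12 cells, where the percentiles with recurrence accounted for were 2.34 and 2.82.

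Tfcp2l1 was the member of the network whose peaks were absent with Ctcf shRNA in each of the 4 sorted populations, a feature chosen after the values were seen. Its peak at the start of the annotated span (chromosome 1, 118627641 to 118628040) was in all 4 sorted control lists and in none of the Ctcf shRNA lists. A further peak at 118622856 to 118623255, outside the gene, was in the SSEA1+ and day 12 control lists. The gene spans 118627923 to 118685168, and day 0 cells had no peak there in either list.

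**Figure D4:**
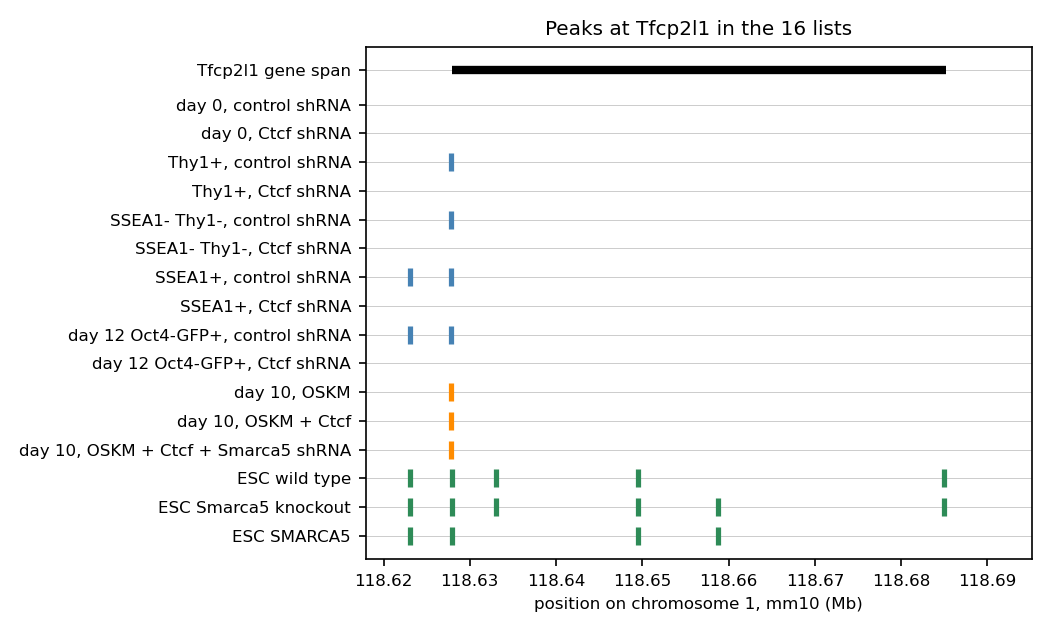
Peaks (ticks) in the 16 lists along the Tfcp2l1 locus, from 10 kb before to 10 kb after the gene span, by position on chromosome 1 of mm10 (Mb, x axis). The 4 sorted control lists have a peak at 118627641 to 118628040 and the 4 sorted Ctcf shRNA lists have none in the window.

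Over the 10 lists and 8 comparisons, 3 of the 80 kept shares lay in the lowest 2.5% of random lists and 10 in the highest 2.5%. The mean number expected by chance is at most 2 in each tail. Without the clustered Hox genes and protocadherins, the counts were 3 and 1 of 64, where the mean expected by chance is at most 1.6. Chance can exceed these means, and the shares are not independent, since the same gene lists recur in each comparison. The kept shares of the trophoblast and primitive endoderm, neural and haematopoietic lists lay in neither tail in any of the 8 comparisons with spans widened by 10 kb, and neither did those of the imprinted genes. This was partly fixed in advance, since the highest tail is out of reach where random lists mostly kept 100% of their peaks. With added Ctcf on day 10, all 10 lists kept 100% and lay at percentiles of at most 87.4. With 50 kb, the neural list in SSEA1+ cells (percentile 98.1) and the imprinted genes in day 0 cells (98.8) lay in the upper tail. Of the 80 shares of new peaks, 9 lay in the lowest 2.5% and 3 in the highest 2.5%, or 3 and 2 of 64 without the Hox genes and protocadherins; they include the imprinted genes on day 10 with added Ctcf and in day 12 cells (0 of 24, percentile 2.06).

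Pluripotent-type and somatic-type sites could be compared only in the populations that did not define them. In SSEA1- Thy1- cells, pluripotent-type sites were kept in 53.8% of 3332 cases and somatic-type sites in 61.8% of 123, a difference of -7.95 points (-13.8 to -2.05, resampling chromosomes). Counting error on both shares gives a wider interval that includes 0 (-16.2 to 1.03), and pluripotent-type sites had the higher share on 7 of 20 chromosomes. In SSEA1+ cells the shares were 57.6% of 4089 and 58.3% of 103, a difference of -0.610 points (-9.81 to 8.10), within the interval. Sites held in all 4 defining lists were kept in 98.3% of cases in both populations. Elsewhere only 1 type can occur: somatic-type sites were kept in 16.9% of 236 cases in day 0 cells and 70.0% of 230 in Thy1+ cells, and pluripotent-type sites in 31.3% of 9149 in day 12 cells.

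Losses in different populations fell on the same sites more often than independent losses would. Over the 10 pairs of populations, the number of sites absent in both Ctcf shRNA lists was 1.73 to 4.86 times the number expected from independent losses, with a median of 2.89. The highest ratio was between SSEA1- Thy1- and SSEA1+ cells, with 3105 shared losses against 638 expected. These cells were sampled on the same days, 6 and 9, which the expected number does not take into account. The lowest was between day 0 and day 12 cells, with 2399 against 1386. No control list was shared between populations. The expected number takes 1 loss rate for all sites of a population. Yet in each population, sites held in all 3 other coordinate sets were lost less often than sites held in none. This can by itself raise the ratio, and expected numbers within recurrence classes were not computed.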

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

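Among the tests in this part, the split of X-linked from autosomal sites and each comparison of knockout-only peaks with SMARCA5 were chosen after the results were seen.

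Sites on the X chromosome were kept less often than autosomal sites in some populations with Ctcf shRNA and more often in another. In day 0 cells 62.7% of X peaks were kept (59.0 to 66.1) against 73.6% on autosomes, and in day 12 Oct4-GFP+ cells 50.1% (47.6 to 52.7) against 58.8%. In Thy1+ cells the X kept more, 85.5% (83.6 to 87.2) against 80.9%, and in SSEA1- Thy1- and SSEA1+ cells the shares were close, 81.2% against 82.1% and 81.5% against 82.0%. Autosomes given the X's mix of recurrence classes ranged from 66.8% to 73.0% in day 0 cells and from 52.3% to 56.4% in day 12 cells, both above the X. The ranges were 75.4% to 79.4% in Thy1+, 74.9% to 79.9% in SSEA1- Thy1- and 75.7% to 79.7% in SSEA1+ cells, all below the X, so the direction turns with this adjustment in SSEA1- Thy1- and SSEA1+ cells. The difference between populations was not tested, and the labels used here give no sex of the cells.

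The length of the CTCF list differed from its reference in opposite directions in the 2 Smarca5 settings, by 7.69% in knockout ESCs and by -1.18% with Smarca5 shRNA on day 10. This difference was not tested. It sets a knockout in an ESC line against a knockdown in reprogramming cells that also overexpress Ctcf, and none of the knockout, wild-type ESC and shRNA lists has a replicate.

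The longer knockout list was weighed further, and neither explanation tested was excluded. Knockout-only peaks held SMARCA5 less often than peaks of both lists, by -13.7 points (-15.01 to -11.8), but that sets rare sites against common ones. Within recurrence classes the signs differed: -1.78 points (-2.86 to -0.588) for sites in 0 other control lists, where most knockout-only peaks lie, 7.49 (3.296 to 11.8) for sites in 1, -12.4 (-24.2 to 1.06) for sites in 2 and -10.4 (-29.2 to 9.22) for sites in 3. Over all classes it was -4.15 (-10.5 to 2.15), with each class weighted by its knockout-only and shared peaks together. That average mostly follows the shared peaks, since only 567 of 8791 knockout-only peaks (6.45%) were in any other control list. Against wild-type-only peaks the difference was 2.22 points (-0.248 to 4.97), so gains at SMARCA5 sites stay open. The 47.5% of SMARCA5 peaks without wild-type CTCF that held CTCF in the knockout add nothing further. They count the same 3107 overlaps from the other side, and no background from shifted peaks was computed for them. A greater depth or a looser threshold in the knockout library also cannot be told apart from a gain of weak sites through loss of Smarca5. Knockout-only peaks were found in control lists of other coordinate sets less often than wild-type-only peaks, by -25.8 points (-27.9 to -23.3), and the bound set for this test before the result was seen was wrong, because a longer list adds rarer sites by itself.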

How the results depend on the processing

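The restriction to recurrent peaks and the comparison within recurrence classes, and part of the restrictions to autosomes and X, were chosen after the data were seen; the other alternatives were planned. Unless stated, the cause of the differences was not tested.

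With peaks found in at least 1 control list of another coordinate set, kept shares were 99.9% for added Ctcf, 99.2% for Smarca5 shRNA and 98.5% for knockout ESCs. With Ctcf shRNA they were 74.5% in day 0, 82.9% in Thy1+, 83.5% in SSEA1- Thy1-, 83.8% in SSEA1+ and 59.7% in day 12 cells. CTCF was then at 97.7% of SMARCA5 peaks and SMARCA5 at 55.6% of CTCF peaks. The rise to 97.7% is largely set by the filter, since the control lists that define recurrence are CTCF lists.

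With a reciprocal overlap of 50%, the day 0 kept share was 72.7%, the day 10 difference between sites with and without SMARCA5 1.96 points, and the ESC minus day 0 share of peaks found only with added Ctcf 65.4 points. Within recurrence classes, the SMARCA5 difference was 0.676 points in ESCs and -0.0491 on day 10, with an interval that includes 0 (-0.280 to 0.179). Leaving out each knockdown pair in turn (leave-one-out) gave mean log2 length ratios of -0.32 to -0.23 and mean kept minus reverse shares of -17.8 to -13.9 points.

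Of 80 gene-list shares, 75 stayed within the spread with spans widened by 2.5 kb and 78 with 50 kb. Their places among random lists moved more: with 2.5 kb, 4 shares left a tail and 0 entered one, and with 50 kb, 2 left and 5 entered. Those leaving with 2.5 kb were fibroblast (percentile 95.8) and Hox genes (87.3) in ESCs, and Hox (92.4) and CTCF, cohesin and ISWI genes (4.76) in SSEA1- Thy1- cells; those leaving with 50 kb were the last of these (2.55) and the pluripotency network in SSEA1+ cells (3.64). Those entering with 50 kb were the pluripotency network (percentile 98.6) and imprinted genes (98.8) in day 0 cells, neural genes in SSEA1+ cells (98.1), protocadherins in SSEA1- Thy1- cells (99.8) and Hox genes with Smarca5 shRNA (99.9).

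No paired analysis was possible because each group has 1 list, in which the samples are pooled; this concerns replicate numbers, and lists were paired by population only. Stricter scores, equal list lengths by score, score quartiles and motif content were not run, since every score is 0 and no genome sequence was used here. Depth per library is not part of the lists, so its effect on list length is open.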

Other observations

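The restriction to recurrence classes, the sites found only with added Ctcf under knockdown, the tests that leave out several genes or weight genes equally, and the test of library strength were chosen after the results were seen.

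The H19 imprinting control region, where CTCF insulates Igf2 from enhancers on the maternal chromosome, had 2 CTCF peaks in most stages. Thy1+ cells kept both with Ctcf shRNA (142580493 to 142580892 and 142581729 to 142582128 on chromosome 7), SSEA1- Thy1- cells had only the first in the control list and kept it, SSEA1+ cells kept the first and not the second, and day 12 cells kept neither. On day 10 both were present with OSKM, with added Ctcf and with added Smarca5 shRNA, and both were in wild-type and Smarca5 knockout ESCs. H19 was named by the rule for day 0 and day 12 cells, and the other populations were looked up after the values were seen.

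Sites that appeared on day 10 only with added Ctcf were kept less often under Ctcf knockdown than sites shared by both day 10 lists. Sites outside these classes were not compared. In day 0 cells 26.8% of 671 such sites were kept against 78.1% of shared sites. In Thy1+ cells 61.5% of the sites found only with added Ctcf were kept against 90.1% of shared sites. The shares were 62.0% against 90.9% in SSEA1- Thy1- cells, 60.1% against 91.9% in SSEA1+ cells and 35.5% against 69.2% in day 12 cells. Among sites alike in their presence in day 0 cells and ESCs, the differences were -10.3, -14.9, -18.4 and -24.3 points. Sites missing from the OSKM list may be weaker ones, which can by itself lower their kept share. Presence in day 0 cells and ESCs does not match sites on strength, and depth of the day 10 libraries is not known. At Nanog, a peak present on day 10 only with added Ctcf (chromosome 6, 122708824 to 122709223) overlaps a day 12 control peak (122709010 to 122709409) that was absent with Ctcf shRNA, a gene chosen after its values were seen.

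Near the pluripotency network, fewer peaks were kept in day 12 cells than near matched genes (42.0%, random median 58.0%). Genes with many peaks do not account for this: the percentile stayed at or below 0.605 whichever single member was left out, was 0.135 without the 5 members with the most peaks, and was 0.305 with every gene given the same weight. Without the 3 members whose removal raises the share most, Tdgf1, Dppa2 and Rif1, picked by their own losses, it was 2.77 (47.4% kept). These genes have many sites that other cell states lack, and a candidate explanation is that such sites are lost more readily wherever they lie. With each peak's expected share taken from its recurrence, the list lay -9.84 points from expectation, against a random median of -0.651 and a percentile of 2.82, just inside the central range. Composition may thus explain part of the day 12 pattern, and a share specific to these genes stays open. The SSEA1+ value (percentile 2.34 after the same adjustment) adds little, since without adjustment it was 4.63 with equal weights, 3.64 with 50 kb and 21.6 without the 5 members with the most peaks.

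The shorter Ctcf shRNA lists could reflect less CTCF on chromatin or shallower libraries, and these cannot be told apart here. Loss of the weakest sites alone would leave sites held in all 3 other coordinate sets nearly complete, if enough other sites are there to be lost. In day 0 cells this was not so: 89.3% of control peaks were of this class, and the 7695 absent peaks outnumber the peaks outside it. The day 0 share of 78.9% was thus largely fixed by the list and decides nothing. Of the day 12 control peaks, 47.8% were of this class. Day 12 cells kept 79.0% of them, whereas Thy1+, SSEA1- Thy1- and SSEA1+ cells kept between 97.8% and 98.6%. A strong enough drop in depth would also remove such sites, and the lists hold neither depth nor peak strength.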
